A study of Oryza sativa with 6 samples.

How the data were processed

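The 6 samples were grouped by their labels into PIF4-GFP (3 libraries) and GFP mock (3 libraries), and replicates carry the numbers of their titles. Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 are named in the submitters' processing notes, with no role or order. The same notes name the mouse build mm8, while the gene identifiers are those of rice. The rice build, the peak caller, its threshold and any pooling of libraries are not given in the sources used here. Coordinates are printed as the deposited list gives them, counted from 1. The list and the expression tables were checked against each other: all 1140 pairs of a peak and a listed gene shared chromosome and strand, and in 933 (81.8%) the distance computed from the gene's start in the tables lay within 500 bp of the distance in the list.

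The deposited tables give one FPKM value per gene and sample, named only by the library in the header, and the unit was taken from the values. Genes at 0 numbered 254 to 264 of 1177 per library. In rows with values in at least 4 samples, the values of all libraries were whole reads divided by 1 length per row and 1 whole total per library, with a largest distance from a whole read of 1.75e-10 and a tolerance of 0.0001. This gave the totals, the implied lengths and the reads. On simulated values for this step the method returned 6 of 6 totals and, for 899 simulated genes, 98.7% of lengths exactly. Nearly all lengths were multiples of 3, so they are read here as coding lengths without untranslated regions. They were not compared with known coding sequences. The mismatch between these lengths and the genes on the rows affects every expression value printed with a gene name, and it does not affect counts over all rows or the peak list.

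The deposited peak list holds locus numbers, start, end, class and distance to the transcription start for each peak, and no score, fold or p-value of a peak. Peak names begin with PIF4-GFP1, and the library or libraries behind them are not given in the sources used here. All but 1 of the 29513 widths were multiples of 200 bp and the smallest gap between neighbours was 800 bp. A width grid of this kind limits how precisely a centre is placed. Peak names are numbered up to 60035, so that 49.2% of the numbers occur in the list, and 0 peaks are classed as intergenic, which makes every share a share of gene-linked peaks.

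Group differences were tested with limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(FPKM + 1), in rows with at least 1 FPKM in 3 or more samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated reads with a spread of 3% between libraries (846 genes in the fit, 200 changed) this recovered 86% of changes of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold, with 14 false calls, 6.80% of all calls. The median SE of that simulation, 0.06 on the log2 scale, is below the 0.10 of the real fit. With a spread of 8%, added after the data were seen to come near the real SE (median SE 0.10, 849 genes), 48% of changes of 1.25-fold, 92% of 1.5-fold and 100% of 2-fold were recovered, with 9 false calls. The simulated spread was independent between genes, while the real libraries also differed in a scale shared by rows. These false calls and recovery rates therefore do not cover a shared scale. The test assumed before the data were examined for normalized values was thus the one used. Single rows also had an exact permutation test. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and for peaks with Fisher's exact test against the other listed genes, with adjustment over the lists of at least 3 members. In 200 random lists of 25 genes the latter gave an unadjusted p under 0.05 in 3.5%. Wilson 95% intervals are given for shares. Peaks were joined to genes by locus number. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Of the 1177 genes, 1057 matched the RefSeq table (assembly ASM3414082v1), which was used for names and to compare gene spans.

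Before the data were examined, 18 gene lists were fixed. Of these, 9 had members among the 1177 genes: light signalling, circadian clock, abscisic acid, drought, heat shock, auxin, other hormones, bHLH factors and pathogenesis-related factors. The other 9 had 0 members: the SAL1-PAP pathway, blue light receptors, guard cell transport, reactive oxygen species, stomatal development, photosynthesis, senescence, ribosomal proteins and root genes. Genes were named by a rule fixed at the same time. It takes PIF4 and SAL1, the 12 largest increases and 12 largest decreases (by mean difference, since 0 rows passed), and up to 4 members with the smallest p in each list; the text gives the leading ones. The part of the rule that ranks peaks by score was not applied, and list members with the positions of their peaks, wide peaks and loci with many peaks were named after the data were seen.

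Alternatives tried were the replicate number as a block, median-centred values, no filter, a filter at 5 FPKM, a pseudocount of 0.1, a fold threshold of 2, leaving out each library, an estimated correlation, and other limits for the promoter. Comparisons of peak sets, motif searches and the SAL1 test were not run.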

Results

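Leaves of potted rice plants, 3 weeks old and kept in fluctuating light with drought, were profiled in 6 libraries, 3 from a PIF4-GFP overexpression line and 3 from a GFP mock. PIF4 is a basic helix-loop-helix (bHLH) transcription factor that acts downstream of the phytochrome photoreceptors, and the tag allows it to be precipitated with its bound chromatin. The series is described as chromatin immunoprecipitation sequencing, whereas the sample labels describe total RNA and a transcriptomic library. The data comprise 1 list of 29513 peaks whose names begin with PIF4-GFP1, and 6 tables of FPKM values for the same 1177 genes, most of them transcription factors. Whether that name stands for replicate 1 or for the line is not given in the sources used here, so the peaks may come from 1 library. The whole-number totals recovered from the FPKM values were 16247094, 17919095 and 17115719 reads for PIF4-GFP replicates 1, 2 and 3, and 15324492, 15186983 and 14933740 reads for GFP mock replicates 1, 2 and 3. The listed genes held between 6.86% and 7.73% of these reads. Nothing in the labels says that replicates came from separate plants or pots, so p-values between the groups measure only the spread between these samples, which may be technical.

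The question of where in the rice genome peaks were called for PIF4-GFP was addressed with the peak list, with no GFP mock peaks to set against it. The listed peaks lay mostly at gene starts: 23278 of the 29513 peaks (78.9%, Wilson 95% interval 78.4 to 79.3%) were classed as promoter, 2442 (8.27%) at transcription ends, 2227 (7.55%) in exons and 1566 (5.31%) in introns. Only 49.2% of the peak numbers up to 60035 are in the list, and 0 listed peaks are intergenic. The shares are thus those of gene-linked peaks, and listed promoter peaks make up 38.8% of all numbers. The peaks named 24592 loci, and 22940 of these had a promoter peak. Promoter peaks were centred 198 bp downstream of the annotated start at the median (quartiles -104 and 512 bp), and 69.2% of their centres lay downstream. These values depend in part on the class limits. The class takes centres up to 1999 bp downstream, while in the gene lists promoter peaks centred upstream all reached the start. Among exon peaks, 1584 of 2227 fell in the last exon and 73 in the first, and all exon and intron peaks were centred more than 2000 bp downstream of the start. Since the classes leave no exon peak nearer the start, the excess of last over first exons partly reflects the class limits. Intervals cover counting error only, and with 1 list there is no replicate error for any value of a peak.

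**Figure D1:**
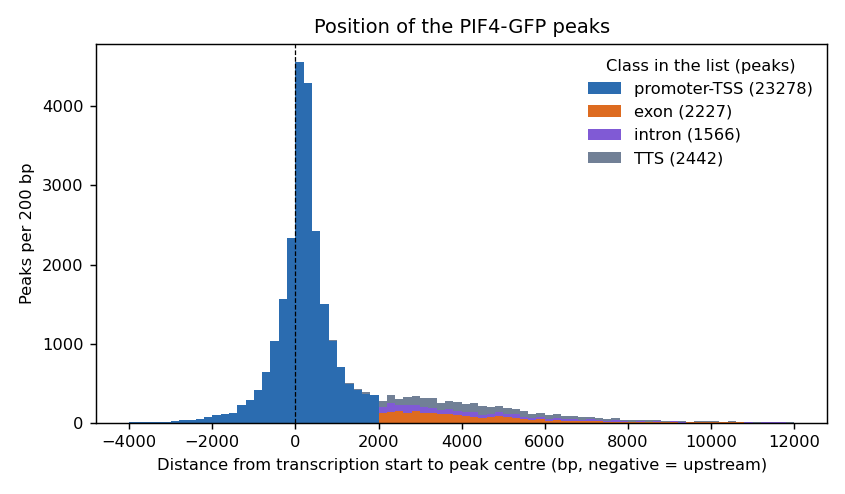
Number of PIF4-GFP peaks per 200 bp (y axis) by the distance in bp from the transcription start to the peak centre (x axis, negative upstream), coloured by the class given in the list, with a dashed line at the start. The promoter class, 23278 peaks with a median of 198 bp, ends at 1999 bp, and exon and intron peaks begin at 2001 bp.

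The peaks were broad. Their median width was 1400 bp (quartiles 800 and 2200 bp), and together they covered 53.1 Mb, 14.2% of the length up to the last peak of each chromosome. Promoter peaks had a median width of 1400 bp, peaks at transcription ends and in introns 1200 bp, and exon peaks 800 bp. The widest peak spanned 37200 bp on chromosome 7, from 18269600 to 18306799, at LOC_Os07g30870. A single peak was assigned to 20237 loci, 2 peaks to 3886 loci and 3 or more to 469 loci. LOC_Os05g18604 on chromosome 5 and LOC_Os08g13880 on chromosome 8 had the most, 8 each. At LOC_Os05g18604 6 of them lay in introns, from 10760600 to 10781599, and 2 at the promoter. At LOC_Os08g13880 7 lay in introns, from 8292400 to 8308399, and 1 at the promoter.

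All 12 rice chromosomes carried peaks, with the density highest on chromosomes 3 (98.6 peaks per Mb), 1 (93.4) and 2 (92.5) and lowest on chromosomes 11 (63.7) and 12 (60.2). On chromosome 2 the 1 Mb from position 1 Mb held 144 peaks and the 1 Mb from 14 Mb held 28. On chromosome 3 the bin from 4 Mb held 143 peaks and the bin from 19 Mb held 21. The sparsest bins, with 17 peaks each, began at 18 Mb on chromosome 6 and at 12 Mb on chromosome 11. As the list holds gene-linked peaks only, these densities may follow the density of genes, which was not compared. The share of promoter peaks stayed between 76.9% on chromosome 9 and 81.0% on chromosome 5.

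**Figure D2:**
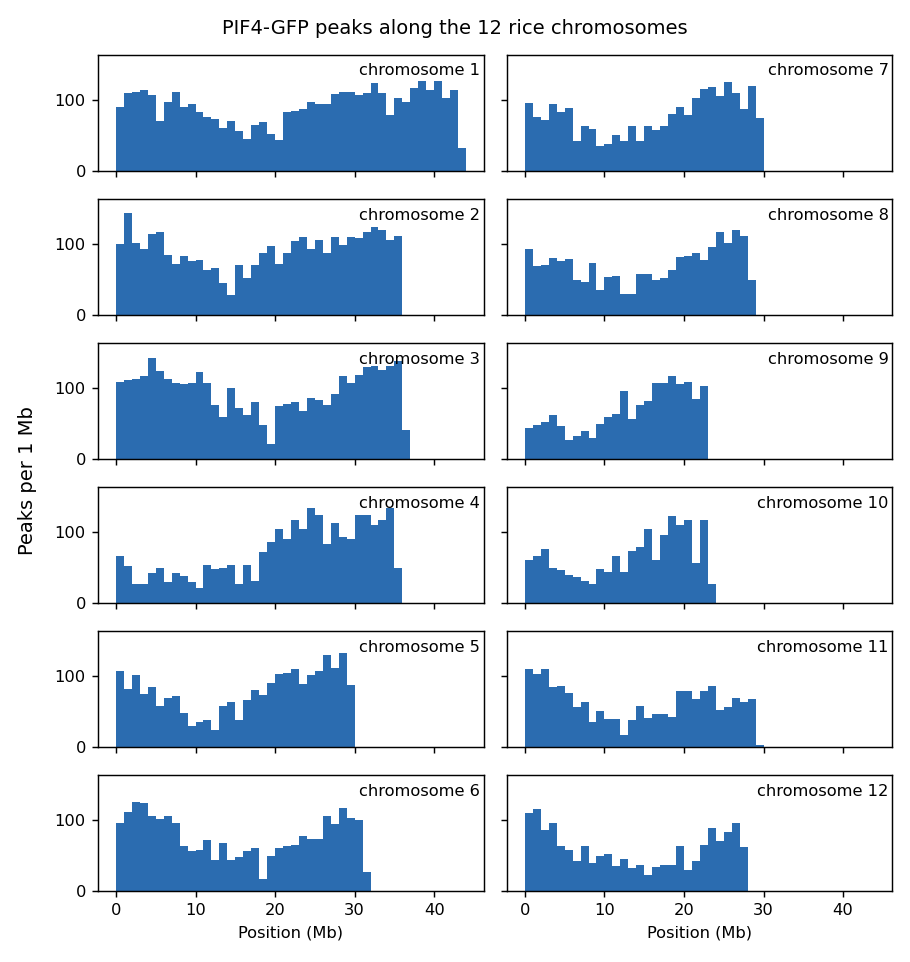
Peaks per 1 Mb (y axis) along each of the 12 chromosomes (x axis, position in Mb); each bar is 1 bin, and the last bin of a chromosome is incomplete. Density falls in the interior of the chromosomes, to 21 peaks on chromosome 3 and 17 on chromosome 11. Only gene-linked peaks are listed, and gene density was not compared.

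Which regulators had a PIF4-GFP peak at their promoter was asked for the 1177 genes of the expression tables, of which 845 (71.8%, Wilson 95% interval 69.2 to 74.3%) did. Of 7 lists tested, the auxin list had the highest share: 24 of 25 members of the auxin list (96.0%, 80.5 to 99.3%) had a promoter peak, against 71.3% of the other genes (Fisher's exact test, two-sided, adjusted p = 0.0191 over 7 lists). The list is made up mainly of auxin response factors, which bind the promoters of auxin-regulated genes, and these as a family had 19 of 20 (Fisher's exact test, adjusted p = 0.361 over 17 families). In the bHLH list, the protein family of PIF4 itself, promoter peaks were less frequent, at 9 of 22 (40.9%, 23.3 to 61.3%) against 72.4% of the others (Fisher's exact test, adjusted p = 0.0191). With a peak of any class counted, the auxin share was still 24 of 25 against 77.0% of the other genes (Fisher's exact test, p = 0.0264, adjusted p = 0.0616), and the bHLH share was 11 of 22 against 77.9% (adjusted p = 0.0286). The bHLH call rests on which members were chosen: with every gene whose description names a helix-loop-helix domain, a wider set chosen after the data were seen, 38 of 55 had a promoter peak (Fisher's exact test, adjusted p = 0.916). Neither call held when a promoter peak had to reach within 2000 bp of the gene's start in the expression tables, a limit also chosen after the data were seen: the auxin list then had 21 of 25 (84%) against 69.2% of the other genes (Fisher's exact test, adjusted p = 0.247), and the bHLH list 9 of 22 against 70.0% (adjusted p = 0.0563).

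In the auxin list, the gene similar to auxin response factor 1 on chromosome 12 (Os12g0479400) had a promoter peak of 6400 bp from 17575800 to 17582199. The peak at the start of the gene similar to auxin response factor 5 (Os05g0563400, chromosome 5, 28033400 to 28035599) was 2200 bp wide. For the gene similar to auxin response factor 12 (Os04g0671900), the list and the tables differ: the peak classed as promoter lies on chromosome 4 from 34284400 to 34285999, while the tables place the gene from 34278549 to 34281440. The exception was Os06g0196700 on chromosome 6, also similar to auxin response factor 1, which had no peak of any class. A pair of auxin rows, Os08g0520500 and Os08g0520550, shared the locus LOC_Os08g40900 and therefore a single peak, on chromosome 8 from 25877000 to 25877999, which lies outside the span of the first in the tables (25870837 to 25871444). In the bHLH list, the gene similar to ICE1 (Os01g0928000), a regulator of the cold response, had a promoter peak on chromosome 1 from 40716400 to 40717199.

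Peaks at light-signalling genes varied in class. The gene similar to HY5 (Os02g0203000), a bZIP factor that promotes seedling development in light, had a promoter peak on chromosome 2 from 5762400 to 5764799 and an exon peak from 5760000 to 5760599. The gene similar to PIF3 (Os12g0610200) had an intron peak on chromosome 12 from 25769800 to 25771999, 2091 bp downstream of its start. The genes similar to PIF4 (Os09g0510500) and HFR1 (Os04g0618600) had none, so that 1 of 4 members had a promoter peak (Fisher's exact test, adjusted p = 0.136). Of the 2 genes in the clock list, the LHY-like gene Os04g0583900 had a promoter peak of 7400 bp on chromosome 4 from 29502400 to 29509799, and Os08g0157600 had none. The gene described as similar to TIMING OF CAB 1 (Os02g0148500), held in the list of other hormones, had a promoter peak on chromosome 2 from 2664200 to 2664999. The only gene in the abscisic acid list, the AREB2-like Os02g0766700, had a promoter peak of 5400 bp on chromosome 2 from 32280400 to 32285799.

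Among drought genes, 7 of 14 had a promoter peak (50%, 26.8 to 73.2%, Fisher's exact test, adjusted p = 0.136). They included the dehydration-responsive element-binding genes similar to DREB1F (Os04g0549700, chromosome 4, 27517000 to 27518599) and the DREB1C gene (Os06g0127100, chromosome 6, 1434200 to 1435599). The neighbouring genes Os09g0522000, Os09g0522100 and Os09g0522200 on chromosome 9, of the same DREB1 group, had no peak. Heat shock factors and chaperones had peaks at 13 of 23 promoters (56.5%, Fisher's exact test, adjusted p = 0.148). In the list of other hormones, 15 of 19 had a promoter peak (78.9%, Fisher's exact test, adjusted p = 0.715). Among them was OsGAI (Os03g0707600), the growth repressor of the gibberellin pathway, on chromosome 3 from 28512200 to 28514999. That list, matched on descriptions and RefSeq names, also took in the TIMING OF CAB 1-like gene, a CCT motif gene and GATA factors, whose descriptions name no hormone. Pathogenesis-related factors had peaks at 12 of 16 promoters (75%, adjusted p = 1).

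The effect of the PIF4-GFP line on transcript levels was addressed by comparing the FPKM tables of the groups, and no row passed the test for a difference. The row described as similar to PIF4 (Os09g0510500) had 7.39 ± 0.499 FPKM in PIF4-GFP and 8.01 ± 0.0121 in GFP mock (mean ± SD, n = 3 each), a log2 difference of -0.10 (SE 0.11, limma adjusted p = 0.895; exact permutation p = 0.1, the smallest that 3 against 3 samples allow). That difference was -0.058 without PIF4-GFP replicate 2 and -0.025 after each library was centred on its median log2 value. The row similar to PIF3 (Os12g0610200) had 23.9 ± 2.60 and 24.4 ± 1.75 FPKM, and the HY5-like row (Os02g0203000) 28.9 ± 2.40 and 29.2 ± 1.51. Of 847 rows tested with limma on log2(FPKM + 1), 0 passed an adjusted p of 0.05 and 33 had an unadjusted p under 0.05, and limma's voom on the recovered reads, added after the data were seen, gave 0 and 46 of 861. These values carry the gene names of their rows, but the lengths behind the values did not follow the genes named there (917 rows compared), so each name is the label of a row and not an identified transcript.

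The 12 highest rows lay between 0.23 and 0.55 on the log2(FPKM + 1) scale, which understates changes of low rows, and 9 of them averaged under 5 FPKM. They were led by rows labelled Os02g0187700 (Myb-related, 3.94 ± 0.895 against 2.52 ± 1.28 FPKM) and Os03g0639600 (similar to the zinc finger protein Lsd1, 2.05 ± 0.146 against 1.26 ± 0.518). Each rests in part on 1 mock library: the log2 difference of Os02g0187700 went from 0.55 to 0.20 without GFP mock replicate 2, and that of Os03g0639600 from 0.46 to 0.26 without GFP mock replicate 3. The 12 lowest rows lay between -0.73 and -0.34, with 6 averaging under 5 FPKM, and were led by homeobox labels: Os09g0466400 (ZF-HD type, 3.28 ± 1.56 against 5.80 ± 0.778 FPKM), Os01g0848400 (BEL1 type, 0.739 ± 0.363 against 1.67 ± 0.277) and Os09g0379600 (HOX25-like, 0.680 ± 0.169 against 1.42 ± 0.342). The size of these differences depends on the pseudocount: with 0.1 in place of 1, Os01g0848400 went from -0.64 to -1.19, Os09g0379600 from -0.52 to -0.96 and Os09g0466400 from -0.73 to -0.90, and voom gave -1.29 for the first. Without PIF4-GFP replicate 1, Os09g0466400 had -0.46. The row with the smallest limma p, Os02g0550900 (FAR1 DNA-binding domain), had 35.1 ± 4.24 against 48.6 ± 5.64 FPKM, a log2 difference of -0.46 (SE 0.10, limma adjusted p = 0.533). In 77 rows (9.09%) the 3 PIF4-GFP values and the 3 GFP mock values did not overlap, where chance gives 10%. Of these rows, 67 were lower in PIF4-GFP and 10 higher, so the total alone hides that most were lower. Rows share the scale of their library and are not independent.

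Rows were also grouped by the gene lists their labels belong to. Because the lengths behind the values followed the labelled genes no better than random pairings, these groups are sets of labels, and a list that did not pass says nothing about the genes it names. In all, 673 of the 847 rows had the lower mean in PIF4-GFP and 174 the higher, and after each library was centred on its median log2 value the counts were 362 lower and 485 higher. Heat shock rows were lower in 14 of 16 cases and in 8 of 16 after centring. Auxin rows were lower in 14 of 15 and in 10 of 15 after centring, and bHLH rows in 10 of 11 and 6 of 11. Drought rows were lower in 8 of 11 and in 2 of 11 after centring. Among them the row labelled Os02g0677300 (similar to CRT/DRE binding factor 1) had 16.7 ± 0.915 against 21.4 ± 1.55 FPKM, a log2 difference of -0.34 (SE 0.09, limma adjusted p = 0.694 over all rows), and was the 1 drought row called when p-values were adjusted over the list alone; 0 rows were called in this way in the other lists. Rows of the other hormones were lower in 13 of 14 cases (6 of 14 after centring), pathogenesis-related rows in 9 of 15 (6 of 15), the light rows in 3 of 3 (1 of 3), the clock rows in 2 of 2 under both and the abscisic acid row under both. The smallest adjusted p of limma's camera over 7 lists was 0.94 with a preset correlation of 0.01, and the adjusted p was 0.965 with an estimated correlation.

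**Figure D3:**
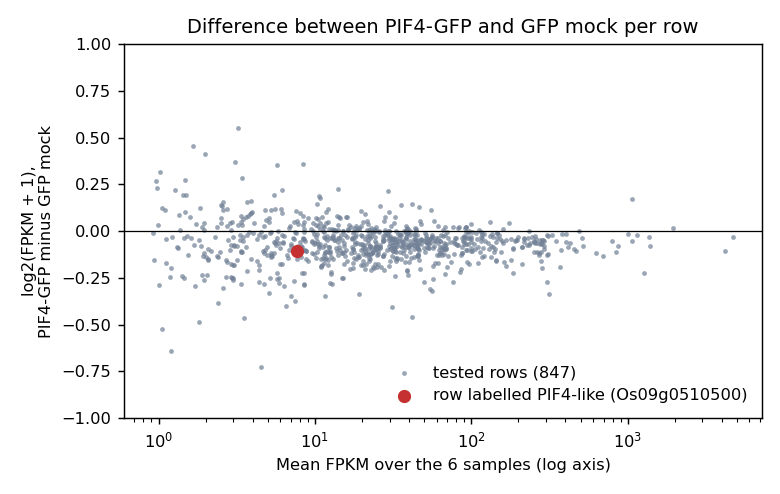
Difference in log2(FPKM + 1) between PIF4-GFP and GFP mock (y axis) against the mean FPKM of the 6 samples (x axis, log scale) for the 847 tested rows, 1 point per row, with the row labelled similar to PIF4 in red. Differences lie between -0.73 and 0.55, and the red point lies at -0.10.

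Apart from their scale, the libraries were close to one another. The spread and the chi-square values given next were computed relative to each library's reads in the listed genes, so they leave scale out. The tested FPKM values were not rescaled in this way. Their sum over the listed genes ran from 60694 to 69416 within PIF4-GFP and from 63810 to 69554 within GFP mock. Beyond counting noise, rows with 500 or more reads varied by a median of 2.72% within PIF4-GFP (400 rows) and 2.11% within GFP mock (373 rows). The pair nearest to counting noise crossed the groups: PIF4-GFP replicate 3 and GFP mock replicate 1 had a mean chi-square of 1.56 per row, where 1 is counting noise alone. Within the groups, PIF4-GFP replicates 1 and 3 had 1.75, GFP mock replicates 2 and 3 had 1.79, and the other within-group pairs lay between 4.71 and 7.71. Without PIF4-GFP replicate 2, limma passed 2 rows, Os07g0586900 (GRAS domain) and Os09g0466400, whose adjusted p with all libraries was 0.895 and 0.694. In that fit limma replaced the spread of each row by that of rows at a like level, so the SE was 0.10 and 0.16 where the rows' own values give 0.39 and 0.42, and the values of Os07g0586900 overlapped between the groups (209 and 225 against 220, 401 and 425 FPKM). Without both PIF4-GFP replicate 2 and GFP mock replicate 1 limma passed 3, with Os04g0540200 (B-box domain, adjusted p = 0.895 with all libraries) added; these libraries were chosen because they resembled the other group, so that count is no independent test. Os07g0586900 and Os04g0540200 were named after their values were seen.

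The lengths behind the FPKM values, read as coding lengths, were compared with the genes named on the rows. All 917 rows with a value in 4 or more samples resolved into whole reads and 1 whole length each, and 916 of these lengths were multiples of 3. Across genes, which are not independent replicates, these lengths had a Spearman rho of 0.0235 with the span of the row's gene (permutation p = 0.484), while spans of the same genes in the RefSeq table had a rho of 0.811 with it (821 genes). The latter compares span with span, so it is not the rho a coding length would reach. No rho for known coding lengths was computed. In 191 rows (20.8%) the length exceeded the whole span of the gene, and random pairings gave 20.5% (18.8 to 22.1%). Rows labelled as auxin response factors had a median length of 900 bp and a median gene span of 5443 bp, and rows labelled LOB domain 1444.5 and 1036.5 bp. Rows whose label had or lacked a promoter peak at its locus, a grouping with the same limit, had median log2(FPKM + 1) values of 3.57 and 3.65, a difference of -0.08 (bootstrap 95% interval -0.63 to 0.36, permutation p = 0.65).

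**Figure D4:**
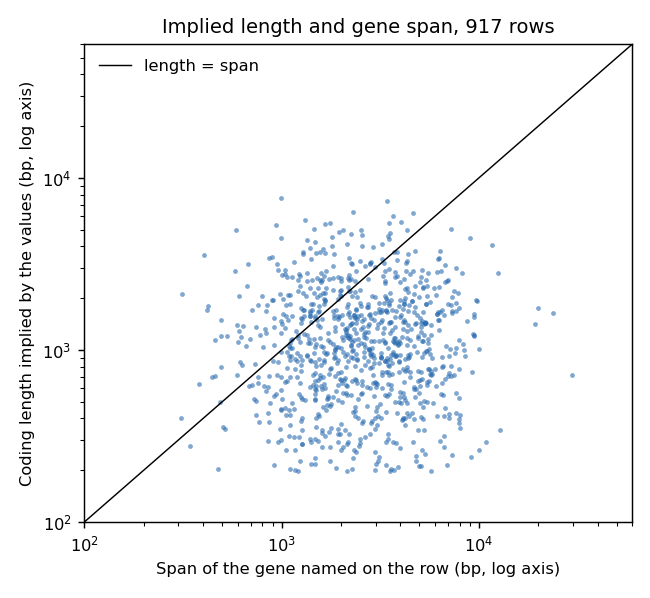
Length implied by the FPKM values in bp, read as a coding length (y axis, log scale), against the span in bp of the gene named on the same row (x axis, log scale) for 917 rows, with a line where both are equal. The points show no trend, with a rho of 0.0235, and 191 lie above the line.

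SAL1, the nucleotidase that breaks down the stress metabolite PAP and the locus the series asks about, was not analysed here, since 0 of the 1177 listed genes carried its name and the peak list gives locus numbers without names. Peaks of the GFP mock and the bHLH binding motifs under the peaks were not analysed here either.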

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

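Tests with voom, without 2 libraries, on wide peaks, on any peak class and with gene starts of the tables were chosen after the data were seen. The count of 0 rows passing between PIF4-GFP and GFP mock stayed at 0 under centring, both filters, the pseudocount of 0.1 and voom; the fold threshold of 2 cannot raise a count of 0. It was 0 to 2 when each library was left out, 3 without both PIF4-GFP replicate 2 and GFP mock replicate 1, and 1 with the replicate block (Os02g0550900, adjusted p = 0.0202, with 89 rows at an unadjusted p under 0.05). Deviations of same-numbered libraries from their group means correlated at 0.111, 0.156 and -0.088. That correlation leaves out a scale shared by rows, so it cannot decide whether the numbers pair the samples. Median FPKM was lowest in replicate 2 (10.2 in PIF4-GFP, 10.6 in GFP mock) and highest in replicate 3 (11.6 in each group). Apart from the fewer libraries, the cause of these moves in the number of passing rows was not tested. The number of lists passing camera was 0 under all 14 alternatives, the block included, with a smallest adjusted p of 0.29; as the lists group rows by labels that did not follow the values, this says nothing about the stability of a gene group. The share of promoter peaks, 78.9% by the class in the list, was 67.1% with centres within 1000 bp of the start on either side, 84.2% within 3000 bp and 82.7% among peaks of at least the median width. The share of listed genes with a promoter peak, 71.8%, was 77.4% with any peak class, 69.5% with promoter peaks near the start in the tables and 44.7% with wide promoter peaks only. With any class 1 of the 2 lists still passed, and the auxin list reached an adjusted p of 0.0616 with 24 of 25 members marked as before, while the share of other genes went from 71.3 to 77.0%. By the starts in the tables, 0 lists passed (auxin adjusted p = 0.247, bHLH 0.0563). Most of the 55 named rows were chosen by their differences or p-values in these data, and the alternatives reuse most of the same libraries. A kept direction is therefore no independent evidence. The block, the filters and the fold threshold leave each difference as it was. Of 533 values of the named rows under the alternatives that recompute a difference, 521 kept their direction. The other 12 lay near 0: centring turned Os12g0610200 to 0.049, Os02g0203000 to 0.063, Os02g0752800 to 0.0019 and Os05g0346200 to 0.027. When any 1 library or both PIF4-GFP replicate 2 and GFP mock replicate 1 were left out, Os12g0610200 ranged from -0.11 to 0.038 (0.0057 without both), Os02g0203000 from -0.070 to 0.063 and Os04g0572400 from -0.14 to 0.022. Alternatives for peak sets, motifs and SAL1 were not run. The median SE on the log2 scale was 0.16 in 140 rows averaging under 5 FPKM and 0.09 in the other 707.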

Other observations

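The large transcription factor families, grouped after the data were seen, were compared by their share of promoter peaks. Promoter peaks stood at 55 of 72 WRKY genes (76.4%, Wilson 95% interval 65.4 to 84.7%), 50 of 73 MYB genes (68.5%), 37 of 55 NAC genes (67.3%), 59 of 82 homeobox genes (72.0%), 25 of 32 bZIP genes (78.1%) and 36 of 51 AP2/ERF and DREB genes (70.6%). Among these and the other families with at least 3 members the highest share was that of the auxin response factors, 19 of 20 (95%), followed by the squamosa promoter binding genes, regulators of flowering and shoot form, at 9 of 10 (90.0%). Among families with at least 3 members the lowest were the heat stress factors, at 12 of 21 (57.1%), and the NF-Y genes, at 4 of 7 (57.1%). None of 17 families differed from the other listed genes (Fisher's exact test, smallest adjusted p = 0.361, for the auxin response factors).

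All tests of the 3 patterns that follow were chosen after the values they concern had been seen, and no biological explanation was tested for the first. The first pattern is that the lengths behind the FPKM values did not follow the genes on their rows. Gene models of another annotation are argued against by the rho of 0.0235 between length and span. A constant shift of the rows is argued against for file, gene and locus order, since the highest rho of 3531 shifts was 0.119, next to 0.115 among as many random pairings. Values and gene labels out of step remain a candidate explanation, as 20.8% of lengths exceeded the gene's span and random pairings gave 18.8 to 22.1%. The values may then belong to other genes of the same table or of the genome, which the tables do not separate.

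The second pattern is that libraries resembled one another across the group labels. With 10 splits of the 6 samples no share under 0.05 can be reached; the real split passed 0 rows and the highest other split 120. That split, PIF4-GFP replicates 1 and 2 with GFP mock replicate 2 against the rest, points to a structure of the samples, and it passed 0 rows after centring, consistent with the overall scale of the libraries. Scale is argued against for the split of PIF4-GFP replicates 1 and 3 with GFP mock replicate 1, which passed 14 rows after centring. An exchange of PIF4-GFP replicate 2 and GFP mock replicate 1 cannot be told apart from an unlabelled batch: the largest mean chi-square within the sets so formed was 4.17 and the smallest across them 4.24, but medians of chi-square, scaled so that 1 is counting noise, did not separate the sets. They were 2.89 within them for PIF4-GFP replicate 2 and GFP mock replicate 3, and 2.02 across them for PIF4-GFP replicate 3 and GFP mock replicate 2. The row labels that would show the transgene are those of the first pattern. The row labelled Os07g0586900 had 209, 225 and 220 FPKM in the first set of that split and 394, 401 and 425 in the other libraries.

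The third pattern is that promoter peaks were centred downstream of gene starts, in 69.2% of cases. Widening of upstream peaks by merged windows could not be decided from narrow peaks. Of the 1266 promoter peaks of at most 400 bp, 90.7% were centred downstream, with a median of 170 bp. The promoter class takes centres up to 1999 bp downstream, and in the gene lists promoter peaks centred upstream all reached the start. If that holds for all promoter peaks, a narrow one had little room to be centred upstream. Removal of peaks away from genes remains a candidate explanation, with 49.2% of peak numbers in the list and 0 intergenic peaks. Such removal could raise the share of promoter peaks, which is 38.8% of all numbers. It could also move their centres downstream if peaks wholly upstream of a start were left out, which was not tested. Binding by PIF4 itself, the biological explanation, cannot be told apart from open chromatin or other background at active genes, since 0 GFP mock peaks were set against these.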
